A study of Mus musculus with 4 samples.

How the data were processed

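Nuclei from mouse kidney cortex were profiled by droplet-based single-nucleus RNA sequencing in 4 genotypes, with 1 library per genotype: wild type (WT), Sco2KO/KI, db/db and Sco2KO/KI;db/db. The strain was C57BL/6J, per the labels. Whether a library held 1 animal or a pool is not given in the sources used here. The reads were processed with Cell Ranger and Seurat against genome build mm10, per the submitters' processing notes. Tool versions, filters on nuclei, the treatment of doublets and the clustering settings are not given in the sources used here, and doublets could not be called from cluster averages.

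The deposited values are a normalised signal, not counts: for each gene, the mean over the nuclei of 1 cluster in 1 library of the UMIs after scaling each nucleus to a total of 10000. The scaling was read from the values, since each of the 83 columns totals 10000 and no value is negative. The name of the deposited table says that unspliced transcripts were included. The table held 21481 entries for 21 clusters. A set of 25 entries carried calendar dates in place of gene names and was left out, since a date cannot be traced to its gene with certainty; these entries held at most 0.307% of a column, with a median of 0.1388%. The remaining 21456 genes were used, and 21117 of their names matched GENCODE vM21, which gave the positions on mm10. All columns were assigned to a genotype by the library code in their names, and 0 columns were left unassigned. Cluster 18 had no column in the Sco2KO/KI;db/db library.

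The deposited table gives no numbers of nuclei or depths. The number of nuclei behind each column was recovered from its lowest values, a step added after the data had been seen. A gene seen as 1 UMI in 1 nucleus has a value of 10000 divided by the product of the number of nuclei and that nucleus's UMI total, so 10000 over the value is a whole multiple of the number of nuclei. The largest number that divided at least 80% of such whole quotients was taken, with a relative tolerance of 1e-10. Tested on simulated data, this gave the exact number for 49 of 51 clusters and for 42 of 42 clusters with 10 or more nuclei. In the 4 libraries the lowest share of quotients divisible by the chosen number was 90.9%. The recovered numbers were used to state how many nuclei a value rests on and to leave small clusters out of the description. They also weighted clusters in 1 alternative and set the size of the simulated libraries described below. UMI totals per nucleus remain unknown, so no counting interval was computed.

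Clusters were named from 23 sets of marker genes fixed before the data were examined, using each cluster's mean over the genotypes against the mean of the other clusters. The names therefore come from markers and may differ from those of the study. Clusters 0, 1, 2, 3 and 7 form the proximal tubule-like class, the main class because the tissue is cortex. Clusters 4, 5, 8, 9, 11, 13, 15, 16, 17, 18, 19 and 20 were named thick ascending limb-like, distal convoluted tubule-like, connecting tubule-like, endothelium-like, type B intercalated cell-like, principal cell-like, podocyte-like, type A intercalated cell-like, parietal epithelium-like, urothelium-like, leukocyte-like and cycling. Clusters 6, 10 and 12 carried markers of more than 1 class and stayed unnamed. Cluster 14 also stayed unnamed: thick ascending limb markers led by this rule, but proximal tubule markers led with the highest other cluster as the reference. Cluster 8 carried 6 of 6 connecting tubule markers but also 8 of 9 principal cell markers. Classes other than the proximal tubule-like class are described only where both libraries of a comparison held at least 20 nuclei, a limit set after the data had been seen.

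For each cluster and comparison the log2 ratio of the values was computed after adding a pseudocount of 0.1, and a class was summarised as the unweighted mean of its clusters' log2 ratios. These ratios are on the log2(value + 0.1) scale, which understates the change of low genes. Genes at or above a floor of 0.5 in the class mean of at least 1 of the libraries compared entered the description. The comparisons were Sco2KO/KI against WT, db/db against WT, Sco2KO/KI;db/db against db/db, Sco2KO/KI;db/db against Sco2KO/KI, Sco2KO/KI;db/db against WT, and the difference of the Sco2 effect between the db/db and the lean background. With 1 library per group no test, p-value, standard error or number of changed genes was computed, and nuclei were not treated as replicates.

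Named genes followed a rule fixed before the data were examined. In the proximal tubule-like class they are the 10 highest and 10 lowest log2 ratios among genes above the floor whose ratio has the same sign in all 5 clusters; genes known only by a model or clone name keep their place but are mostly not described. In every other class they are the 3 highest and 3 lowest. Across classes they are the 5 genes with the highest and the 5 with the lowest median log2 ratio over all named classes, those with fewer nuclei than the limit included, among genes above the floor in each of them; these medians are not described. For the difference of the Sco2 effect they are the 5 highest and 5 lowest. Some genes that these rules name are not reported here. Of each gene list, the members with the largest absolute log2 ratio were named. Sco2, Lepr and the sex-linked genes were always included. A gene is called higher or lower where its absolute log2 ratio is at least 1, which is a size and not a test.

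A further set of 30 gene lists was fixed before the data were examined, covering the respiratory chain, stress responses, metabolism, transport, signalling, injury and inflammation. A list was described where at least 4 members were above the floor. Its median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries. A list of male-biased and a list of female-biased proximal tubule genes were added after the data had been seen and are used only in the additional observations.

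The ratio and list steps were tested on simulated data for db/db against WT, with 200 of the genes changed by known folds among 3753 genes above the floor. The right sign was recovered for 50 of 50 genes at each size. The median recovered log2 ratios were -1.71 and -0.96 for genes set to -2 and -1, and 0.93 and 1.89 for genes set to 1 and 2. All 20 genes named by the rule were among those changed by 2 on the log2 scale. Both simulated libraries were drawn from the WT means, so differences between animals, preparations or amounts of carried-over RNA were not simulated. They had the numbers of nuclei recovered for db/db and WT and assumed UMI totals, so the smaller Sco2KO/KI library was not simulated. Of 200 lists drawn from unchanged genes, 23 had a percentile under 5 or over 95.

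The alternatives fixed before the data were examined were pseudocounts of 0.02 and 0.5, no floor, a floor of 1.0, rescaling of each column with and without the mitochondrially encoded genes, centring on the median gene, the median over clusters, leaving out each proximal tubule-like cluster in turn, 20 expression bins for the random lists, and the highest other cluster as the reference for cluster names. A class mean weighted by nuclei was chosen after seeing the data. A number of named genes kept was taken as stable where the full number was at most 1.5 times as large, and a ratio or list median where it moved by less than 1 standard deviation over the clusters of the class. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.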

Results

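Single-nucleus RNA sequencing of kidney cortex covered 4 mouse genotypes with 1 library each. They were wild type (WT), Sco2KO/KI, db/db and the double mutant Sco2KO/KI;db/db. Sco2 is a mitochondrial copper chaperone needed to assemble cytochrome c oxidase, and KO/KI stands for a knockout and a knock-in allele. db/db mice lack the signalling form of the leptin receptor Lepr and become obese and diabetic. The libraries held 5157 nuclei in WT, 1182 in Sco2KO/KI, 4578 in db/db and 5279 in Sco2KO/KI;db/db, recovered from the lowest values, and the UMI totals behind them are unknown. There were no replicates, so no difference between genotypes was tested, and the values describe these 4 libraries only. Levels are mean UMIs per 10000 in a nucleus, given as normalised values.

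The proximal tubule-like class held 2447, 706, 2003 and 3015 nuclei in the same order of genotypes. Its nuclei were spread differently over its clusters: cluster 0 was the largest of the 5 in WT, with 683 nuclei, and cluster 1 in Sco2KO/KI;db/db, with 1005. Cluster 7, which carried markers of the straight segment, held 441 nuclei in WT and 30 in Sco2KO/KI;db/db, so that its values in the double mutant rest on few nuclei. These nuclei also differed in marker levels, with Slc34a1 at 12.5 in WT and 26.4 in the double mutant, Cyp7b1 at 26.6 and 2.71 and Slc7a13 at 25.3 and 8.33, and cluster 7 has the same weight in a class mean as each of the other 4. Clusters 6, 10, 12 and 14 belonged to no class. Cluster 6 held 312, 79, 319 and 242 nuclei, cluster 10 held 254, 21, 270 and 111, cluster 12 held 134, 32, 141 and 204, and cluster 14 held 161, 21, 116 and 34.

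The mutated genes themselves could not be used to check the genotypes. Sco2 (chromosome 15, 89371637 to 89373846, minus strand, mm10) was below the floor in the proximal tubule-like class of every library, at 0.034 in WT, 0.0216 in Sco2KO/KI, 0.011 in db/db and 0.018 in Sco2KO/KI;db/db. Lepr (chromosome 4, 101717404 to 101815352, plus strand) was found mainly in the endothelium-like class, at 0.570, 1.31, 0.490 and 0.241. Among sex-linked genes, the Y-linked Uty was present in all 4 libraries at 3.24, 3.5, 2.89 and 2.95 in the proximal tubule-like class, and Ddx3y at 1.26, 1.11, 1.02 and 0.919. Xist, the X-inactivation transcript, was at most 0.0124 there. Nnt, a mitochondrial transhydrogenase gene that is partly deleted in C57BL/6J mice, was at most 0.01 in the proximal tubule-like class. Its highest level in any class was 0.186, in the 15 type A intercalated cell-like nuclei of Sco2KO/KI.

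Transcripts of the proximal tubule were also found in other classes. Kap, an abundant androgen-regulated transcript of the proximal tubule, reached 48.0 in the endothelium-like class of WT, against 43.3 in the proximal tubule-like class itself. Its endothelium-like level was 59.1 in Sco2KO/KI, 5.83 in db/db and 5.78 in Sco2KO/KI;db/db. Slc34a1, the phosphate transporter of the proximal tubule, was at 11.6, 11.7, 5.17 and 9.22 in that class. In the other direction Slc12a1, the salt transporter of the thick ascending limb, was at 2.64, 0.996, 1.21 and 0.811 in the proximal tubule-like class.

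The comparison of Sco2KO/KI with WT addressed the Sco2 mutant genotype in lean mice. In the proximal tubule-like class, transcripts of the mitochondrial genome lay above WT as a group, though by different amounts: mt-Nd2, a complex I subunit, was at 8.15 in WT and 24.5 in Sco2KO/KI, and mt-Atp8, an ATP synthase subunit, at 0.905 and 3.40, log2 ratios of 1.58 and 1.79, while the cytochrome c oxidase subunits mt-Co1, mt-Co2 and mt-Co3 had 0.52, 0.45 and 0.54. Genes of fatty acid oxidation lay above WT as a group, led by the peroxisomal enzyme Ehhadh with 0.538 in WT and 1.29 in Sco2KO/KI. The matrix phosphoprotein gene Spp1, whose product osteopontin marks stressed tubules, was lower, at 2.91 and 0.632, a log2 ratio of -2.21. The log2 ratio of Spp1 was negative in all 13 named classes, small ones included, from -4.98 to -0.16. Less carried-over RNA would also give a drop in every class, and it was not separated from these values. The highest log2 ratio was that of Npas3, a neuronal transcription factor gene (chromosome 12, 53248677 to 54072175, plus strand), at 0.035 in WT and 4.17 in Sco2KO/KI, a log2 ratio of 4.96 that ranged from 4.37 to 5.50 over the 5 clusters.

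Other genes higher in Sco2KO/KI in all 5 proximal tubule-like clusters were the collagen gene Col6a6 (log2 ratio 3.22), the glucuronosyltransferase gene Ugt1a10 (2.79), the cadherin gene Pcdh7 (2.38), Angptl7 (2.18), the phosphodiesterase gene Pde1a (1.72) and Lonrf3 (1.42). Ugt2b38, another glucuronosyltransferase gene, was at 2.31 in WT and listed at 0 in Sco2KO/KI in each of the 5 clusters. Lower genes were the immunoglobulin gene Ighm (-2.23), Cyr61, a matrix protein gene induced by YAP (-2.04), the carboxypeptidase gene Cpn1 (-2.02), the growth factor gene Pdgfd (-1.78), the sodium-calcium exchanger gene Slc8a1 (-1.77), Erlin1 (-1.65), the calcineurin regulator Rcan1 (-1.63) and Atp8b4 (-1.60). Slc8a1 is a connecting tubule transcript, at 296 in cluster 8, and carried-over RNA was not separated from its value here, nor from that of Pdgfd. Ighm rested largely on cluster 0, without which its log2 ratio was -1.47.

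Of the gene lists, the mitochondrially encoded genes had the highest median log2 ratio in Sco2KO/KI against WT, 1.06, with 12 of 12 genes above the floor positive. That median lay at percentile 100 among random lists matched on expression, a description of these libraries and not a test. As the libraries were made from nuclei, transcripts of the mitochondrial genome reached them from outside the nucleus. Nuclear genes of the same respiratory complexes did not move with these transcripts. The nuclear subunits of cytochrome c oxidase, the complex that needs Sco2, had a median of -0.04, with 4 of 8 genes positive and Cox6a1 at -0.56. ATP synthase subunits had a median of -0.12 over 12 genes, complex I subunits -0.21 over 11, and complex II and III subunits -0.24 over 10. Fatty acid oxidation and PPAR alpha targets had a median of 0.32 at percentile 100, with 16 of 19 genes positive, among them Ehhadh (1.11), Cyp4a10 (0.96), Cpt2 (0.55) and Slc25a20 (0.51). Without a floor on low genes this median was 0.191.

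Glycolysis genes above the floor, 5 of the 18 measured, were on the lower side in Sco2KO/KI. All 5 were negative, with a median of -0.41 at percentile 4.66, led by Gpi1 (-0.50) and Ldha (-0.46). Distal salt transport genes, which belong to other nephron segments, had a median of -0.38 at percentile 0.27, with Slc8a1 at -1.77 and Slc12a1 at -1.36. Proximal tubule transport and endocytosis genes had a median of -0.10 over 24 genes. Immediate early and heat shock genes, which respond to tissue handling, had a median of -0.99 at percentile 0.0, with 7 of 7 negative, including Dusp1 at 1.10 in WT and 0.309 in Sco2KO/KI. That median was -0.504 with a pseudocount of 0.5 and -0.533 without a floor. The integrated stress response list, which mitochondrial dysfunction can activate, had a median of -0.14 over 6 genes, with Sesn2 at 0.68 and Atf4 at -0.34. Hypoxia response genes had a median of -0.31 over 4 genes, led by Vegfa (-0.48).

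Medians of the remaining lists in Sco2KO/KI against WT were -0.24 for cholesterol synthesis, where Insig1 was at -0.90, -0.17 for the NRF2 antioxidant response, -0.14 for fatty acid synthesis, where Scd1 was at 1.12 and Acly at -0.92, and -0.14 for the p53 list. Mitochondrial protein folding and proteases had -0.13, with Hspd1 at -0.81, and extracellular matrix and fibrosis -0.07. Sex-linked genes had -0.07, gluconeogenesis -0.04 and mitochondrial biogenesis regulators -0.04. Mitochondrial dynamics and mitophagy genes had -0.003, as had copper and metallothionein genes. The circadian list had 0.10 and the renin-angiotensin and insulin/leptin list 0.05, with the angiotensin receptor gene Agtr1a at -1.11. Cox assembly and copper delivery, tubular injury, interferon response, NF-kB inflammation and haemoglobin had fewer than 4 genes above the floor in the proximal tubule-like class, and haemoglobin in every class.

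The mitochondrially encoded genes were also above WT in the other classes of Sco2KO/KI with at least 20 nuclei in both libraries. Their median log2 ratio was 0.44 in the thick ascending limb-like class, 0.73 in the distal convoluted tubule-like class, 0.65 in the connecting tubule-like class, 0.72 in the endothelium-like class and 0.70 in the principal cell-like class. Proximal tubule markers in those same classes had medians of 0.09, -0.18, -0.24, -0.06 and 0.41.

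**Figure D1:**
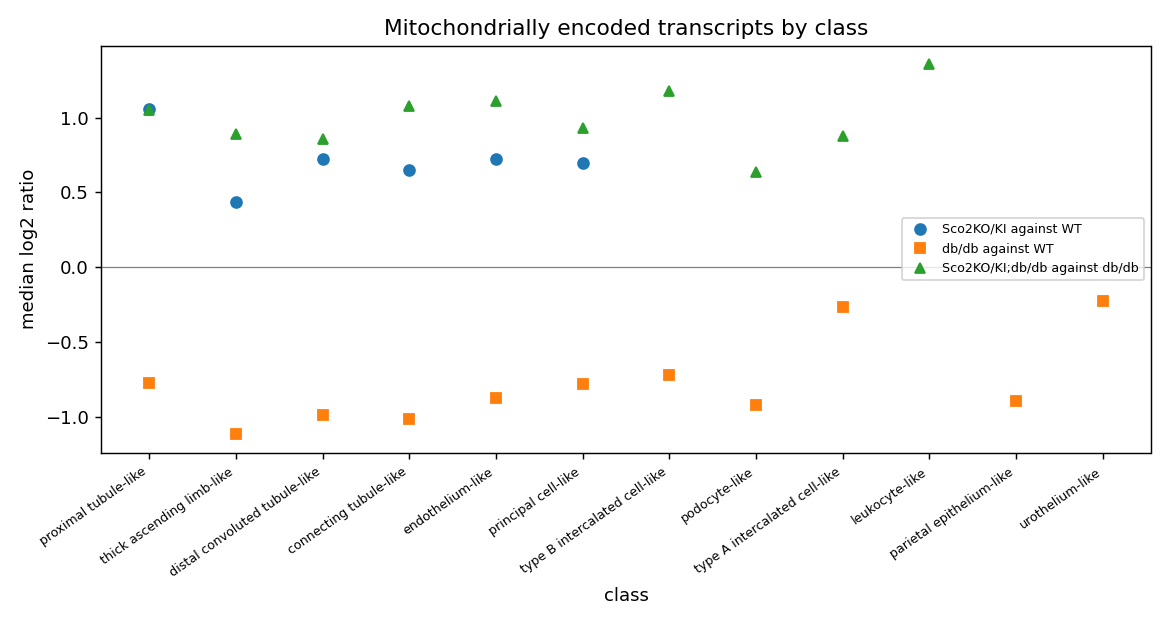
Median log2 ratio of the mitochondrially encoded genes (vertical axis) in each named class with at least 20 nuclei in both libraries (horizontal axis), for Sco2KO/KI against WT (circles), db/db against WT (squares) and Sco2KO/KI;db/db against db/db (triangles). In the proximal tubule-like class the medians were 1.06, -0.77 and 1.05.

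The comparison of db/db with WT addressed the db/db genotype with Sco2 intact. In the proximal tubule-like class of db/db, the fatty acid hydroxylase gene Cyp4a14, a PPAR alpha target (chromosome 4, 115486200 to 115496142, minus strand), was higher, at 0.013 in WT and 0.737 in db/db. The androgen-regulated Kap was lower, at 43.3 and 6.58, as were the amino acid transporter gene Slc7a13, at 12.4 and 2.99, and the cytochrome gene Cyp4b1, at 14.4 and 2.41, log2 ratios of -2.77, -2.90 and -2.44. Mitochondrially encoded genes lay below WT as a group, with mt-Nd4 at 9.67 and 4.25. Slc7a13 is among the genes that define cluster 3.

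Further genes higher in db/db in all 5 clusters were Npas3 (0.035 and 1.99, log2 ratio 3.95), the efflux transporter gene Abcc4 (1.53 and 7.81, 2.40), the collagen gene Col27a1, the glutamine transporter gene Slc38a3 (2.17), Cadps2 (2.12), Zbtb38 (2.03) and the netrin receptor gene Dcc (2.00). Col27a1 was at 2.19 in WT and 11.4 in db/db. Further lower genes were Tmem252 (-2.93), the cytokine gene Il34 (-2.46), the transcriptional repressor gene Bcl6 (-2.37), the lipoprotein lipase gene Lpl (-2.28), the aminoacylase gene Acy3 (-2.26) and Ighm (-2.22). The log2 ratio of Ighm was -1.46 without cluster 0. The organic anion transporter gene Slc22a7 was at 0.955 in WT and listed at 0 in db/db.

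Mitochondrially encoded genes had a median log2 ratio of -0.77 in db/db against WT, at percentile 0.0, with 12 of 12 negative. Among nuclear respiratory lists, ATP synthase subunits had a median of -0.40 at percentile 0.06 with 10 of 12 negative, and nuclear cytochrome c oxidase subunits -0.42 at percentile 1.57 with 6 of 7 negative, including Cox8a at 1.55 in WT and 0.56 in db/db. Complex II and III subunits had a median of -0.21, with 10 of 10 negative, and complex I subunits -0.04 at percentile 25.3, with 7 of 12 negative. Regulators of mitochondrial biogenesis were positive in 5 of the 5 genes above the floor, with Esrra at 0.77 and Ppargc1b at 0.54, but 16 were measured, and the median went from 0.435 to 0.163 without a floor. The cytochrome c oxidase median was -0.241 with a pseudocount of 0.5 and -0.265 without a floor. Carried-over RNA was not separated from these nuclear lists. In the other classes the mitochondrial list was also below WT, with a median of -1.12 in the thick ascending limb-like class and -0.87 in the endothelium-like class, and proximal tubule markers in those classes were at -1.04 and -1.01. The 2 did not always go together: the mitochondrial median was -0.72 with markers at -0.18 in the type B intercalated cell-like class, and -0.22 with markers at -1.08 in the urothelium-like class.

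Fatty acid oxidation genes went both ways in db/db against WT. Their median was 0.17 at percentile 87.5, with 14 of 21 positive, Cyp4a14 at 2.79, Cyp4a10 at 1.75 and Cyp4b1 at -2.44. With a floor of 1.0 this median was -0.003. Cyp4a14 lies within 20 Mb of Lepr. A chromosome segment carried along with the Lepr mutation therefore cannot be told apart from other sources of its value, here and in the double mutant. Cholesterol synthesis genes were negative in 5 of 5, with a median of -0.72 at percentile 0.39, led by the sterol sensor partner Insig1 (-1.96) and the sterol demethylase Cyp51 (-1.36). The glutathione transferase genes Gsta2 and Gsta3 of the NRF2 list were higher, at 1.85 and 1.39, while that list as a whole had a median of 0.16. Integrated stress response genes had a median of -0.45 at percentile 2.46, with Atf4 at -0.60 and Ddit3 at -0.53, and this was -0.15 without a floor and -0.266 without cluster 1. Glycolysis genes had a median of -0.39, with Tpi1 at -0.71. Immediate early and heat shock genes had a median of -1.80 at percentile 0.0, with Egr1 at 0.533 in WT and 0.049 in db/db, and -0.837 without a floor.

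Transport genes of the proximal tubule had a median of 0.07 in db/db against WT with members far apart, 13 positive and 12 negative, the lowest being Slc7a13, Kap and Slc22a7, followed by Slco1a1 (-2.17). Sgk1, a kinase of salt balance, was higher at 1.62, in a distal salt transport list with a median of 0.00. Epas1 and Hif1a of the hypoxia list were at 1.08 and 0.76 while that list had a median of -0.14. The gluconeogenesis list had a median of 0.04, with the glutamate dehydrogenase gene Glud1 at 0.98. In the circadian list, with a median of 0.27, Nr1d1 was at -1.20 and Cry2 at 0.94. Medians of the other lists lay between -0.17 for sex-linked genes and 0.18 for copper and metallothionein genes.

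**Figure D2:**
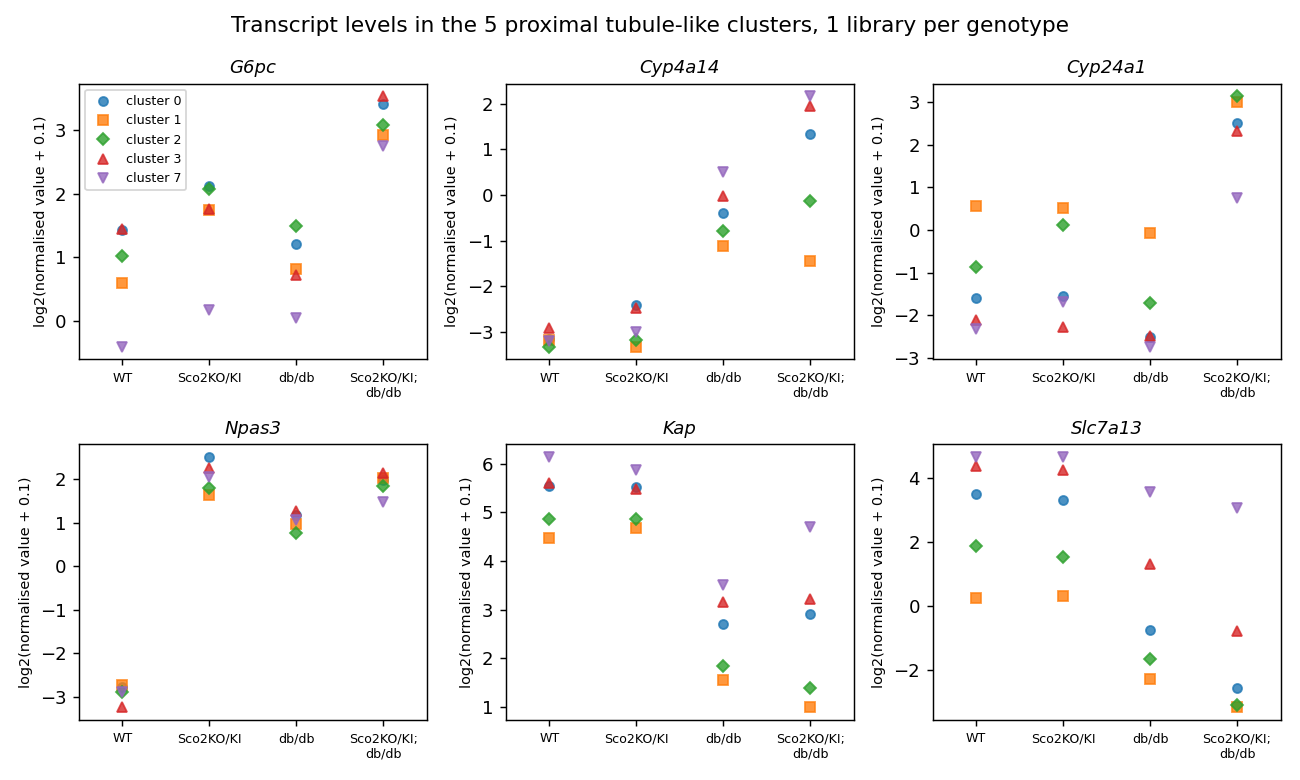
Levels of 6 genes on a log scale, log2 of the normalised value plus 0.1 (vertical axes), in the 5 proximal tubule-like clusters (symbols) of each genotype (horizontal axes), with 1 library per genotype. Class means of Cyp24a1 were 0.455, 0.574, 0.251 and 5.70 and those of Kap 43.3, 40.8, 6.58 and 9.43 in WT, Sco2KO/KI, db/db and Sco2KO/KI;db/db.

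The comparison of Sco2KO/KI;db/db with db/db addressed the Sco2 mutant genotype on the db/db background. In the proximal tubule-like class, Cyp24a1, the enzyme that inactivates vitamin D (chromosome 2, 170482708 to 170497145, minus strand), was at 0.251 in db/db and 5.70 in the double mutant, a log2 ratio of 4.24 that ranged from 3.07 to 5.00 over the 5 clusters. G6pc, the last enzyme of glucose release, was at 1.81 and 8.90. Genes of fatty acid oxidation and of the mitochondrial genome lay above db/db as groups, with Ehhadh at 0.701 and 2.70 and mt-Co1 at 8.07 and 22.8. The predicted gene Gm42397 (chromosome 7, 70870913 to 71073345, plus strand) was at 14.1 and 0.383, a log2 ratio of -4.72.

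Other genes higher in the double mutant than in db/db in all 5 clusters were Sesn2, a stress-induced inhibitor of mTORC1 (2.25), Pced1b (2.15), Cyp4b1 (1.99), the vitamin D-dependent calcium binding protein gene S100g (1.93), the glucose-responsive thioredoxin inhibitor Txnip (1.87) and Sugct (1.82). S100g is a connecting tubule marker, at 16.3 in cluster 8 against 2.17 in the other clusters, and carried-over RNA was not separated from its value. Lower genes were Pcdh7 (1.83 and 0.231, -2.49), Wsb1 (-1.97), the kinase gene Nuak2 (-1.61), Map3k7cl (-1.61), the fatty acid translocase gene Cd36 (2.66 and 0.983, -1.60), the neurotrophin gene Bdnf (-1.59), Lrrc28 (-1.56) and Cadps2 (-1.52).

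Mitochondrially encoded genes had a median log2 ratio of 1.05 in Sco2KO/KI;db/db against db/db, at percentile 100, with 12 of 12 positive. Nuclear respiratory lists differed in how far they went with them, least for complex I subunits, with a median of 0.12 and 6 of 11 positive. Nuclear cytochrome c oxidase subunits had a median of 0.66 at percentile 99.9, with 7 of 7 positive, led by Cox8a (1.25) and Cox6a1. ATP synthase subunits had a median of 0.61 at percentile 100, with 11 of 12 positive, and complex II and III subunits 0.30, with 10 of 10 positive. The last of these was 0.134 without cluster 7, and the cytochrome c oxidase median was 0.251 without a floor and 0.408 with a pseudocount of 0.5. In the other classes the mitochondrial list had medians from 0.64 in the podocyte-like class to 1.36 in the leukocyte-like class, which held 20 nuclei in db/db. Proximal tubule markers in these classes were at 0.54 and 1.66. In the type B intercalated cell-like class the mitochondrial median was 1.18 and that of proximal tubule markers -0.59. Carried-over RNA was not separated from the medians of the nuclear respiratory lists either.

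Fatty acid oxidation and PPAR alpha targets had a median of 0.70 in the double mutant against db/db, at percentile 100, with 23 of 25 positive. Examples were Ehhadh (log2 ratio 1.63) and the carnitine transferase gene Cpt1a (1.01), while Cd36 was lower. The median was 0.460 with a pseudocount of 0.5 and 0.376 without a floor. Among proximal tubule transport genes, several were higher, with the glucose transporter gene Slc5a2 at 1.64 and 4.12, the amino acid transporter gene Slc6a19 at 0.964 and 2.03 and the inositol oxygenase gene Miox at 3.51 and 7.73, in a list with a median of 0.09 in which Slc7a13 was at -1.35. Slc5a2 and Slc6a19 are among the genes that define clusters 1 and 2.

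Gluconeogenesis genes had a median of 0.19 in the double mutant against db/db, with G6pc at 2.29 and Gpt2 at -0.82. Integrated stress response genes were positive in 5 of 5, with a median of 0.20 in which Sesn2 stood apart. The insulin receptor substrate gene Irs2 was at 1.20 in the renin-angiotensin and insulin/leptin list, whose median was 0.26, and Ndrg1 at 1.42 in the hypoxia list, whose median was -0.15. Fatty acid synthesis genes had a median of -0.28, with Acly at -0.64, and biogenesis regulators -0.30, with Nrf1 at -0.56. In the NRF2 list, with a median of 0.14, Gclc was at -1.11. Calb1 of the distal salt transport list was at 1.39, and that list had a median of -0.08. Medians of the other lists lay between -0.11 for copper and metallothionein genes and 0.25 for circadian genes. Cholesterol synthesis and immediate early genes had fewer than 4 members above the floor.

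The comparison of Sco2KO/KI;db/db with Sco2KO/KI addressed the db/db genotype in Sco2 mutant mice. In the proximal tubule-like class, Cyp4a14 was again higher on the db/db side, at 0.04 in Sco2KO/KI and 2.33 in the double mutant, a log2 ratio of 3.65. The tryptophan catabolism enzyme gene Kynu was at 0.646 and 5.28. Lower transcripts were Slc7a13 at 11.5 and 1.78, Kap at 40.8 and 9.43, and the anion transporter gene Slco1a1 at 2.23 and 0.094. Slco1a1 and Slc7a13 are among the genes that define cluster 3.

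Other genes higher in the double mutant than in Sco2KO/KI were Cyp24a1 (3.31), Kynu (2.92), the glycine cleavage enzyme gene Gldc (2.88), Abcc4 (2.86), the growth factor receptor gene Erbb4 (2.45), the glucocorticoid-induced Fkbp5 (2.26) and Txnip (2.25). Ugt2b38 was listed at 0 in Sco2KO/KI and was at 0.752 in the double mutant. Lower genes were Gm42397 (27.7 and 0.383, -5.69), Pcdh7 (-3.24), the fatty acid hydroxylase gene Cyp4a12a (-2.71), Cntnap5a (-2.36), Angptl7 (-2.24) and Acsm3 (-2.20).

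Fatty acid oxidation and PPAR alpha targets had a median of 0.55 in Sco2KO/KI;db/db against Sco2KO/KI, at percentile 100, with 22 of 25 positive, including the uncoupling protein gene Ucp2 (1.90) and Acaa2 (1.77). Mitochondrially encoded genes had a median of -0.64 at percentile 0.0, with 12 of 12 negative and mt-Nd2 at -1.64. Nuclear respiratory lists had positive medians, 0.31 for ATP synthase with 9 of 12 positive and 0.29 for complex II and III with 8 of 10. Those of complex I, 0.20 with 6 of 10 positive, and of cytochrome c oxidase, 0.16 with 5 of 7, lay at percentiles 87.6 and 75.1, inside the range of most random lists. Without cluster 7, the ATP synthase median was 0.153 and that of complex II and III 0.131. NRF2 targets had a median of 0.55 at percentile 99.95, with Gsta2 at 1.97 and the quinone reductase gene Nqo1 at 1.40, and 0.199 without a floor. Gluconeogenesis genes were positive in 9 of 9, with a median of 0.29, led by G6pc (1.57) and the glucose-6-phosphate transporter gene Slc37a4 (1.19).

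Distal salt transport genes had a median of 0.50 in that comparison, with Calb1 (2.04) and Slc8a1 (1.91). These belong to other segments, and the connecting tubule-like class held 33 nuclei in Sco2KO/KI and 319 in the double mutant. RNA carried over from other segments was not separated from these values. Transport genes of the proximal tubule had a median of 0.27 with 13 of 23 positive, which was 0.042 without cluster 7. The cholesterol synthesis list depended on cluster 7, with a median of -0.59 over 5 genes, led by Cyp51 (-1.65), that became 0.202 without it. Biogenesis regulators were positive in 5 of 5 with a median of 0.23, and mitochondrial dynamics genes in 9 of 9 with a median of 0.15. In the fatty acid synthesis list, with a median of -0.16, Scd1 was at -1.29. Medians of the other lists lay between -0.24 for sex-linked genes and 0.35 for the renin-angiotensin and insulin/leptin list. Hypoxia, glycolysis, p53 and immediate early genes had fewer than 4 members above the floor.

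**Figure D3:**
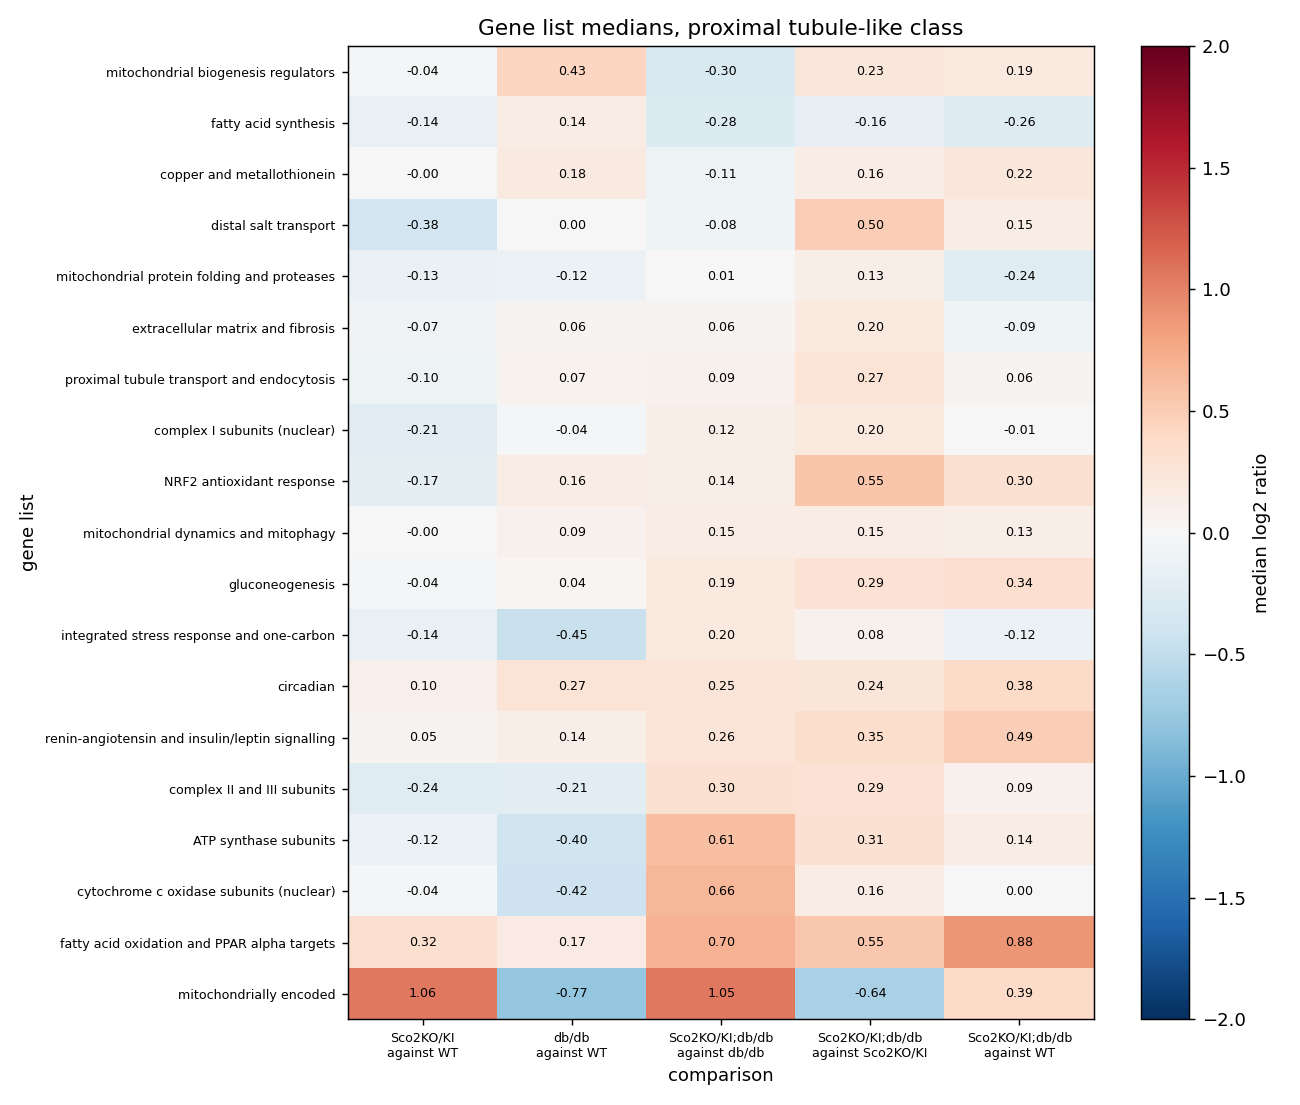
Median log2 ratio (colour and printed value) of the gene lists described in all 5 comparisons (vertical axis) for each comparison (horizontal axis) in the proximal tubule-like class. The mitochondrially encoded list was positive in both comparisons of Sco2KO/KI genotypes with their Sco2-intact counterparts, 1.06 and 1.05, and fatty acid oxidation was highest in the double mutant against WT, 0.88.

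The comparison of Sco2KO/KI;db/db with WT addressed the combined genotype. Among single genes of fat metabolism and glucose release that were higher in the proximal tubule-like class of the double mutant were Cyp4a14 at 0.013 in WT and 2.33, the lipase inhibitor gene Angptl4 at 0.097 and 1.04, and G6pc at 1.84 and 8.90. Their log2 ratios were 3.92, 2.42 and 2.33. Cyp24a1, at 0.455 and 5.70, was also higher (3.60). The transporter genes Slc7a13, at 12.4 and 1.78, and Slco1a1, at 2.02 and 0.094, were lower (-4.25 and -3.21).

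Other genes higher in the double mutant than in WT were Npas3 (4.8), Abcc4 (2.71), Gldc (2.60), the glutathione transferase gene Gsta2 (2.41) and Kynu (2.29). Lower genes were Gm42397 (-5.36), Kap (-2.68), the chaperone gene Hsph1 (-2.55), the phospholipid flippase gene Atp11a (12.7 and 2.67, -2.51) and the cell death gene Bik (0.52 and 0.008, -2.51). Slc22a7 was at 0.955 in WT and listed at 0 in the double mutant.

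Fatty acid oxidation and PPAR alpha targets had a median of 0.88 in the double mutant against WT, at percentile 100, with 21 of 25 positive, and it was 0.602 without a floor. Mitochondrially encoded genes had a median of 0.39, with 11 of 12 positive, and nuclear cytochrome c oxidase subunits 0.00, with 4 of 8 positive. Gluconeogenesis had a median of 0.34 at percentile 98.2 and the renin-angiotensin and insulin/leptin list 0.49 at percentile 98.9, with Irs2 at 1.05. Without a floor these medians were 0.189 and 0.206. The circadian list had a median of 0.38 at percentile 99.4, with Cry2 at 1.32 and Per2 at 0.88. NRF2 targets had a median of 0.30, with Gsta3 at 1.52, which was 0.048 without a floor. Cholesterol synthesis had a median of -0.63, with Cyp51 at -1.70, and -0.141 without cluster 7. Immediate early and heat shock genes had a median of -1.48 at percentile 0.0, with Egr1 at -2.31 and Jun at -1.95, and -0.687 without a floor.

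Medians of the other lists in the double mutant against WT lay between -0.27 for sex-linked genes and 0.22 for copper and metallothionein genes. In the fatty acid synthesis list, with a median of -0.26, Elovl6 was at 1.06 and Me1 at -0.86. Oma1, a mitochondrial stress protease gene, was at 0.98 in a protein folding and protease list with a median of -0.24. Slc12a1 was at -1.98, Sgk1 at 1.47 and Calb1 at 1.11 in the distal salt transport list, with a median of 0.15.

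The difference of the Sco2 effect between the db/db and the lean background addressed whether the db/db background alters what goes with the Sco2 mutant genotype. The difference was positive for Cyp24a1, whose log2 ratio to its Sco2-intact counterpart was 0.29 in lean and 4.24 in db/db mice, a difference of 3.94. It was also positive for Spp1 (-2.21 and 0.94, a difference of 3.16), Sugct (-1.30 and 1.82, 3.12) and Erbb4 (-1.04 and 1.93, 2.97). It was negative for Gm42397 (0.33 and -4.72, -5.05), Pcdh7 (2.38 and -2.49, -4.87), Npas3 (4.96 and 0.85, -4.11), Ugt1a10 (2.79 and -0.72, -3.52) and Gm3448 (1.13 and -1.43, -2.56). These differences were not tested, as they rest on 4 single libraries. Npas3 and Ugt1a10 were low only in WT, at 0.035 and 0.007, so their differences rest on that library.

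As a group, mitochondrially encoded genes had a median difference of -0.01, with 5 of 12 positive. Nuclear respiratory genes had a median difference of 0.71 for ATP synthase subunits (10 of 12 positive, percentile 100), 0.49 for complex II and III, 0.47 for cytochrome c oxidase (7 of 8 positive, percentile 98.5) and 0.26 for complex I. Examples were Cox6a1 at 1.62 and Atp5g3 at 1.40. Against WT, ATP synthase and cytochrome c oxidase subunits had medians of -0.40 and -0.42 in db/db and 0.14 and 0.00 in the double mutant. Much of their differences thus goes with low values in the db/db library. Carried-over RNA was not separated from the nuclear respiratory lists in any comparison. The ATP synthase difference was 0.388 without cluster 7 and that of cytochrome c oxidase 0.269 with a pseudocount of 0.5. Fatty acid oxidation genes had a median difference of 0.44 with 19 of 25 positive, including Ucp2 at 2.09. Glycolysis genes were positive in 5 of 5, with a median difference of 0.64 that was 0.257 without a floor and 0.378 without cluster 0.

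Immediate early and heat shock genes had a median difference of 0.78 with 7 of 7 positive, led by Dusp1 at 2.69, and 0.487 with a pseudocount of 0.5. Cholesterol synthesis had a median difference of 0.49, with Insig1 at 2.23, and distal salt transport 0.39, with Calb1 at 2.32. Proximal tubule transport had a median difference of 0.07 over 25 genes, with Slc6a19 at 1.92 and Miox at 1.72. The other lists lay between -0.21 for biogenesis regulators and 0.30 for the renin-angiotensin and insulin/leptin list.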

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

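The tests in this part were all chosen after the results had been seen. Among the 10 genes named for the largest difference between backgrounds in the proximal tubule-like class, 6 had log2 ratios of the Sco2 mutant genotype in opposite directions on the lean and the db/db background in each of the 5 clusters. Other genes were not checked for this, the 10 were chosen for the contrast itself, and this difference was not tested, since each genotype had 1 library. Spp1 had log2 ratios of -2.21 on the lean and 0.94 on the db/db background, a difference of 3.16. Sugct had -1.30 and 1.82, a difference of 3.12. Gm42397 had 0.33 and -4.72, a difference of -5.05. Pcdh7 had 2.38 and -2.49, a difference of -4.87. Ugt1a10 had 2.79 and -0.72, a difference of -3.52. Gm3448 had 1.13 and -1.43, a difference of -2.56.

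Ugt1a10 belongs to a wider pattern of 18 transcripts that were below 0.05 in at least 1 library and above 0.5 in another, such as Npas3, Ugt2b38, Cyp4a14, Ighm and Bik, and a candidate explanation is variation between animals or breeding lines. The genotypes stay open. For 50% of these genes the pairs of libraries with and without a mutation lay at least 1 log2 unit apart. These were 8 by the db/db and 1 by the Sco2 genotype, and 0 were apart by the pairing that follows neither. With the stricter levels that define the pattern, below 0.05 and above 0.5 in every library, only 1 of the 18, Cyp4a14, followed a genotype, so this evidence depends on the limit chosen. Chromosome segments carried along with either mutation are argued against for the genes on other chromosomes, such as Npas3, Ugt1a10, Ugt2b38 and Slc22a7. Only 2 of the 18, or 11.1%, lie within 20 Mb of Lepr or Sco2. For these, Cyp4a14 and Bik, such segments cannot be told apart from other sources. The breeding history of each allele is not given in the sources used here. Differences between single animals, lines or nuclear preparations were not tested and stay open.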

How the results depend on the processing

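The number of named genes that remained under an alternative ranged from 12 to 20 of 20 for Sco2KO/KI against WT, db/db against WT and Sco2KO/KI;db/db against db/db, from 15 to 20 for Sco2KO/KI;db/db against Sco2KO/KI, from 13 to 20 for Sco2KO/KI;db/db against WT and from 6 to 10 of 10 for the difference of the Sco2 effect between backgrounds. A pseudocount of 0.02 kept 13 for db/db against WT, 12 for Sco2KO/KI;db/db against db/db, 13 for Sco2KO/KI;db/db against WT and 6 for the difference. A pseudocount of 0.5 kept 13 for Sco2KO/KI against WT and 12 for db/db against WT, and a floor of 1.0 kept 12 for Sco2KO/KI against WT. In the other 77 cases the number stayed within 1.5 times.

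Median log2 ratios of the mitochondrially encoded genes kept their direction in all 5 comparisons under every alternative, with ranges of 0.994 to 1.109 for Sco2KO/KI against WT, -0.870 to -0.658 for db/db against WT and 0.954 to 1.140 for Sco2KO/KI;db/db against db/db. With a pseudocount of 0.5 the cytochrome c oxidase median was -0.241 for db/db against WT, and the fatty acid oxidation median 0.460 for Sco2KO/KI;db/db against db/db and 0.653 for Sco2KO/KI;db/db against WT. Without a floor the fatty acid oxidation medians were 0.191 for Sco2KO/KI against WT, 0.376 for Sco2KO/KI;db/db against db/db and 0.602 for Sco2KO/KI;db/db against WT, and the cytochrome c oxidase medians -0.265 for db/db against WT and 0.251 for Sco2KO/KI;db/db against db/db. With a floor of 1.0 the fatty acid oxidation median for db/db against WT was -0.003. Leaving out each cluster in turn gave fatty acid oxidation differences between backgrounds from 0.365 to 0.640, the latter without cluster 1. The cholesterol synthesis median for Sco2KO/KI;db/db against Sco2KO/KI ranged from -0.678 to 0.202, and reversed only without cluster 7. The cause was not tested in any of these cases.

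Among list medians, the mitochondrially encoded, cytochrome c oxidase and fatty acid oxidation lists and lists at extreme percentiles were followed under alternatives. Of these medians, 554 moved by less than their spread over clusters, 42 by more and 1 reversed. A reversal was counted only for lists at extreme percentiles, so sign changes near 0 in other lists are not in that count. The cytochrome c oxidase median of Sco2KO/KI against WT, for example, ranged from -0.080 to 0.039. Of the values of single named genes, 1437 moved by less than their spread and 103 by more. The leading marker set was the same for 16 of 21 clusters with the highest other cluster as the reference. The mean weighted by nuclei was chosen after seeing the data. No paired analysis was possible because each genotype had 1 library, and no replicate could be left out. Few nuclei limit the precision of values from the Sco2KO/KI library, with 1182 nuclei, and of cluster 7 of Sco2KO/KI;db/db, with 30. UMI totals are unknown, so no limit of detection could be set for genes below the floor, Sco2 among them.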

Other observations

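The tests in this part were all chosen after the results had been seen. Outside the proximal tubule, the protease gene Ctse was high in the collecting duct of both db/db genotypes. In the principal cell-like class it was at 0.057 in WT, listed at 0 in Sco2KO/KI, and at 18 in db/db and 10.6 in Sco2KO/KI;db/db, and it is among the genes that define that cluster. In the connecting tubule-like class it was listed at 0 in WT and Sco2KO/KI and was at 4.13 in db/db and 2.30 in the double mutant, and in the type A intercalated cell-like class it was listed at 0 in WT and was at 2.88 and 4.06. The connecting tubule-like class also carried 8 of 9 principal cell markers, so principal cells within it may hold this transcript. In the endothelium-like class of the double mutant, Zbtb16, a glucocorticoid-induced transcription factor gene, was at 13.2 against 1.21 in WT, and Igf1 at 0.133 against 3.96. In the podocyte-like class, the calcineurin regulator gene Rcan2 was at 0.407 in WT and 5.48 in db/db, and the channel gene Trpc6 was listed at 0 in WT and was at 1.11 in db/db.

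The thick ascending limb-like class held large differences in membrane and cell-surface protein genes that are among those defining its cluster. Sgcz was at 22.9 in WT, 0.224 in Sco2KO/KI, 0.251 in db/db and 1.43 in Sco2KO/KI;db/db. Nrxn3 was at 5.57, 15.6, 0.442 and 17.8, and Enox1 at 5.53, 12.5, 31.2 and 24.2. Levels of Cyp24a1 were also higher in the double mutant than in db/db in the nuclei of other classes, at 0.714 against 0.031 in the thick ascending limb-like class, 0.616 against 0.020 in the distal convoluted tubule-like class and 0.867 against 0.044 in the endothelium-like class. RNA carried over from the proximal tubule-like class, where it was at 5.70, was not separated from these values, and Kap, a proximal tubule transcript, was at 5.78 in the endothelium-like class of the double mutant against 9.43 in its proximal tubule-like class. Among the clusters without a name, cluster 12 carried Slc8a1 at 605, 612, 805 and 902 and Calb1 at 19.2, 24.5, 41.3 and 67.4 in WT, Sco2KO/KI, db/db and the double mutant, and cluster 10 carried both Slc34a1, at 35 in WT, and Slc12a3, at 46.1.

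Mitochondrially encoded transcripts lay above their Sco2-intact counterparts as a group in both Sco2KO/KI genotypes. In lean mice, more free RNA that carries proximal tubule markers is argued against. These markers had a median log2 ratio of -0.06 in 5 other classes, with an SD of 0.26 over classes, where at least 0.35 was needed. The principal cell-like class, at 0.41, went the other way. So did Kap, which is not among the markers, at 48.0 in WT and 59.1 in Sco2KO/KI in the endothelium-like class. The SD is over classes of the same 2 libraries and does not measure a spread between animals. On the db/db background that median over classes was 0.39 with an SD of 0.69 over 9 classes, where 0.47 was needed. This explanation cannot be told apart from the others there, as the classes spread too widely. Free RNA rich in mitochondrial transcripts but not in these markers was not tested on either background. As the libraries were made from nuclei, transcripts of the mitochondrial genome reached them from outside the nucleus, and the carried-over amount was not measured. More mitochondrial RNA carried into every droplet of a library stays a candidate explanation. Of the 16 pairs of class and background, 93.8% had a list median above 0.5, but an effect of Sco2 in every cell type predicts the same value. An effect of Sco2 stays open and was not tested against differences between single preparations.

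A hypothesis for the lower Kap, Slc7a13 and Slco1a1 in both db/db genotypes is weaker androgen action, since 11 of 11 genes known to be higher in male proximal tubules had negative log2 ratios to WT, with medians of -1.57 in db/db and -2.09 in the double mutant, but this list was chosen after the levels of its genes had been seen and so counts for little by itself. Female animals under the db/db labels are argued against, since the lower of the medians of Ddx3y and Uty was -0.27. The highest list median of any single proximal tubule-like cluster was -1.40, so changed shares of the clusters do not by themselves give the lower values. Fewer nuclei of the straight segment still cannot be excluded, because RNA carried over between clusters was not separated. Cluster 7, with markers of that segment, held 441 nuclei in WT, 242 in db/db and 30 in the double mutant. Weaker androgen action itself cannot be told apart from obesity, diabetes or differences between single animals, which were not tested: genes higher in females had medians of 1.04 in db/db and 0.26 in the double mutant, but these rest on 3 genes, 1 of them chosen after its level was seen, and mainly on cluster 7, and Slc7a12 was at -0.10 in the double mutant. In Sco2KO/KI against WT the genes higher in females had a median of 0.34, and those higher in males -0.05 with 9 of 11 negative.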
